A study of Mus musculus with 6 samples.

How the data were processed

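Gene expression was measured on Illumina mouse bead arrays in Th9, Th1 and Th17 cells, with 2 arrays per kind and 6 in all. Per the labels, the cells were sorted as CD45.1 and CD4 positive from spleens of tumour-bearing mice 12 days after transfer, and total RNA was amplified to biotin-labelled cRNA. The values used are the array intensities of the deposited value table, on a linear scale. That scale was read from the values themselves, which centre near 0 and fall below it in every array, as after subtraction of a background. The authors' own background and scaling method for these deposited intensities is not given in the sources used here. Another deposited table holds 6 signal and 6 detection columns whose names match no sample label. No mapping was guessed, so those columns, and with them the detection p-values, were not used.

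The groups, comparisons, gene lists, naming rule and alternatives were fixed before the data were examined. The design foresaw that detection p-values might be missing, and the fallback was followed: background correction by normexp with an offset of 50, quantile normalization and log2. Detection was replaced by a noise rule, which the design had not stated. A probe counted as detected on an array when its intensity exceeded 1.645 times the root mean square of the values below 0 on that array, which corresponds to a p of 0.05 on the side above background. Probes detected on at least 2 arrays were kept, 22460 of 45281. Thresholds lay between 5.84 and 6.95 intensity units, and 18581 to 20466 probes were detected per array. The median intensity per array lay between 3.7 and 4.8, so a median probe is near background.

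Probes were named with current gene symbols, 28620 through the gene identifier, 2637 through the transcript accession, 2128 through the symbol and 2343 through a synonym, and 56 symbols were kept as given. A further 9497 probes had no gene. Of the kept probes 18614 had a name and 3846 did not, of which 197 (Th9 against Th1), 414 (Th9 against Th17) and 331 (Th17 against Th1) passed when all kept probes were tested. Each gene was represented by its probe of highest average level, which left 12093 genes. For named genes, 211 values of other kept probes were compared with the probe used. In 85 the other probe did not pass where the used probe did, and in 1 it passed in the opposite direction (Cd8b1).

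The comparisons Th9 against Th1, Th9 against Th17 and Th17 against Th1 were made in 1 linear model over the 6 arrays with limma 3.58.1 in R 4.3.3, with moderated t statistics (3 residual and 16.2 prior degrees of freedom, median residual SD 0.104) and Benjamini-Hochberg adjustment within each comparison at 0.05. Genes called in both Th9 comparisons in the same direction were counted as apart from both. Arrays were not paired by repeat, as planned, since the word repeat is not stated to mark a shared batch. In a later check, the deviations of the repeats from their group means had correlations of -0.021, -0.023 and 0.014 between groups. Where the lower group was detected on 0 arrays, the change is given as at least the fold over the detection threshold.

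Gene lists written beforehand covered helper subset programmes, cytotoxic, memory, regulatory, follicular, inhibitory receptor, signalling and metabolic genes, and markers of other cell types. Of 513 entries in 24 lists, 382 were measured. A melanocyte list had 3 of 10 members measured, under the minimum of 5, and was not tested. The other 23 lists were tested with camera at its preset correlation of 0.01, adjusted over 69 tests, and again with a correlation estimated per list, with which 0 lists passed. The estimated version rests on the 3 residual degrees of freedom, which limits how small its p-values can be. That 0 lists passed it over 69 tests therefore does not decide whether a list shifted. Named genes were up to 10 each way with the largest change whose arrays did not overlap, up to 4 called members of each list, and 16 key genes. Predicted genes with only a provisional symbol were passed over, so statements on the largest changes leave those out.

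The gene and list tests were tried on simulated data. Normal values were drawn around the normalized levels of the filtered genes, with the spread estimated by the model itself. Background correction, scaling and the detection rule were not part of the simulation, so its recovery does not speak to those steps. Genes planted at a log2 change of 0.5 were recovered in 77.6, 83.6 and 80.6% of cases in the 3 comparisons and those at 1 and 2 in 100%, with 8, 8 and 17 of 11893 unchanged genes called. A list planted at a shift of 0.3 passed in each comparison, with 0 of 22 other lists. The simulated genes were drawn independently, so this does not test the list procedure where genes of a list are correlated. Alternatives changed the background correction, scaling, filter, probe summary, variance model, arrays fitted, fold threshold and list test, and left out each array in turn. In the setting without background correction, values below 1 were set to 1 after quantile normalization, and no offset was added. Dim probes then vary more on the log2 scale. A call that ends there therefore need not come from the background correction. Figures were drawn with matplotlib 3.10.9.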

Results

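Gene expression was measured on Illumina bead arrays in mouse CD4 T helper cells that had been transferred into tumour-bearing C57BL/6 mice and were recovered from the spleen 12 days later by sorting on CD45.1, a cell-surface marker of the donor cells, together with CD4. T helper cells are the CD4 lymphocytes that direct other immune cells through cytokines. 3 kinds were compared: Th1, a subset defined by interferon gamma and the transcription factor T-bet, Th17, a subset defined by interleukin 17, and Th9, a subset defined by interleukin 9. Each kind was represented by 2 arrays, 6 in all. The labels call the other array of each kind only a repeat, so the p-values given here rest on the spread between these arrays, which may be technical. That spread was mostly pooled over genes rather than a gene's own, with 16.2 prior against 3 residual degrees of freedom. The number of arrays, not a read depth, limits the precision. Between 41 and 45.2% of the 45281 probes were above background on an array, and the mean intensity of an array lay between 117.1 and 171.1. After filtering, 12093 named genes were tested. Log2 fold changes are on the scale of log2 intensity after background correction with an offset of 50, which understates the change of dim genes. Their standard errors were between 0.106 and 0.145 for the named genes, with n = 2 arrays per kind throughout.

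Across probes, which are not independent replicates, the arrays of one kind had a Pearson correlation of 0.9943 for Th9, 0.9926 for Th1 and 0.9949 for Th17, against 0.9698 to 0.9801 between kinds. The standard deviation of the probe-wise log2 differences was 0.16 to 0.193 within a kind and 0.315 to 0.388 between kinds. The leading principal components held 52.6, 29.8 and 7.18% of the variance. The arrays of a kind are not copies of each other, and each was counted. These values do not show whether they are biological or technical repeats.

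The defining cytokine of Th9 cells was not detected, so it could not be compared between the subsets. The Il9 probe lay below the detection threshold on 6 of the 6 arrays, at 4.1 and 3 intensity units in Th9, 1.8 and 0.1 in Th1, and 0.1 and 0.4 in Th17, against thresholds of 5.84 to 6.95. Spi1, which encodes the transcription factor PU.1, and Klrg1, a receptor of late effector T cells, were each above the threshold on 1 array and were not tested. Tcf7 was not analysed here. Il17a, the cytokine that names the Th17 subset, passed the filter but stayed near background and did not pass the test in any comparison, with log2 fold changes of -0.07 (Th9 against Th1), 0.03 (Th9 against Th17) and -0.11 (Th17 against Th1).

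The comparison of Th9 with Th1 cells asks how these recovered subsets differ. Th9 cells had higher levels of Il4, the signature cytokine of type 2 helper cells, which was at least 12.2-fold higher because Th1 cells were not above background. Gata3, the transcription factor of type 2 helper cells, was higher by a log2 fold change of 2.58 ± 0.11, and Irf4, a transcription factor needed for Th9 differentiation, by 1.35 ± 0.11. Th9 cells had lower levels of Il18r1, a receptor chain for interleukin 18 (-3.11 ± 0.13), of Cxcr3, a chemokine receptor of Th1 cells (-2.48 ± 0.11), and of Tbx21, which encodes T-bet (-1.0 ± 0.12). The Tbx21 call ended without background correction (-4.32, adjusted p = 0.157). Another Il18r1 probe, near background, gave -0.34 and did not pass, though against Th17 it passed (-0.47). The largest increase was that of Akr1c18, an enzyme that inactivates progesterone, which was at least 20.7-fold higher in Th9, again against a Th1 level not above background.

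Other genes with the largest increases in Th9 over Th1 were Myo6, an unconventional myosin (4.08 ± 0.12), Hba-a1, an alpha globin gene (2.99 ± 0.11), Penk, which encodes the opioid peptide precursor proenkephalin (2.66 ± 0.11), Tent5a (2.29 ± 0.11), St6gal1, a sialyltransferase (2.18 ± 0.13), Asb2 (2.15 ± 0.13) and Pros1, which encodes protein S (2.14 ± 0.11). Those with the largest decreases also included Plac8 (-2.81 ± 0.11), Onecut2 (-2.52 ± 0.12), Gbp2, an interferon-induced GTPase (-2.45 ± 0.11), Ms4a4b (-2.26 ± 0.12), the MHC class I gene H2-Q8 (-1.92 ± 0.11), Gpr18 (-1.91 ± 0.11), Hsd11b1 (-1.81 ± 0.11) and Irgm2, another interferon-induced GTPase (-1.78 ± 0.14). Of the 2 other Onecut2 probes 1 gave -2.73 and the dimmer gave -0.003, which did not pass. Onecut2 was above background on 1 of the 2 Th9 arrays, so the size of its change depends on the floor. Akr1c, guanylate-binding protein, Ms4a4 and MHC class I genes belong to families with near-identical members, so which member the probe read is uncertain.

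Of 12 measured members of the Th1 list, 8 were lower in Th9 and 0 higher, over all genes as well as adjusted over the list alone (camera adjusted p = 4.16e-09, or adjusted p = 0.0569 with an estimated correlation). Besides Il18r1, Cxcr3 and Tbx21 they included Ccl5, a chemokine (-0.85), and Ifng, the interferon gamma gene, which was at least 1.38-fold lower in Th9, where it was not above background. That call for Ifng ended without Th9 replicate 2 (adjusted p = 0.0502), with arrays scaled to their median (adjusted p = 0.0503) and without background correction (-2.61, adjusted p = 0.273). Of 12 measured members of the Th9 and type 2 helper list, 7 were higher and 1 lower, and 9 were higher and 1 lower adjusted over the list alone (adjusted p = 2.76e-10, or adjusted p = 0.0569 with an estimated correlation). They included Il24, an interleukin 10 family cytokine (1.65), beside Il4, Gata3 and Irf4.

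Of 23 measured interferon response genes, 11 were lower in Th9 than in Th1 and 0 higher, and 15 were lower adjusted over the list alone (adjusted p = 8.94e-12, or adjusted p = 0.0569 with an estimated correlation). They included Igtp (-1.75), Gbp3 (-1.66) and Usp18, a protease that removes ISG15 (-1.43). Of 12 measured regulatory T cell genes, 9 were higher and 0 lower, and 10 were higher adjusted over the list alone (adjusted p = 2.52e-14, or adjusted p = 0.0569 with an estimated correlation). Those with the largest change were Gpr83 (1.84), Itgae, the integrin alpha E chain (1.64), Nrp1, neuropilin 1 (1.45), and Tnfrsf4, the costimulatory receptor OX40 (1.29), which activated helper cells also express. Foxp3, the factor that defines regulatory T cells, did not pass against Th1 (0.29) or Th17 (0.03), nor did Ikzf2, both named after their values were seen. The 1 other Gpr83 probe, near background, gave -0.07 and did not pass, and of 4 other Itgae probes 1 passed (1.87). Of 18 measured memory and quiescence genes, 6 were lower and 0 higher, against 9 lower and 1 higher adjusted over the list alone (adjusted p = 0.000202, or adjusted p = 0.0932 with an estimated correlation). Cd27, a costimulatory receptor of less differentiated T cells, changed by -1.30.

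Of 20 measured immediate early and heat shock genes, 6 were higher in Th9 and 0 lower, also adjusted over the list alone (adjusted p = 0.000599, or adjusted p = 0.0994 with an estimated correlation). Those with the largest change were the early growth response factors Egr3 (1.79), Egr2 (1.55) and Egr1 (1.18) and the AP-1 subunit Fos (1.05). Such genes also respond to the handling of cells. Another Egr3 probe, near background, gave 0.14 and did not pass. Of 20 homing and adhesion genes, 3 were higher and 7 lower, and 4 were higher and 8 lower adjusted over the list alone (adjusted p = 0.0263, or adjusted p = 0.385 with an estimated correlation). The chemokine receptor Ccr8 was at least 1.78-fold higher in Th9, whose Th1 level was not above background, and Cxcr6, another chemokine receptor, was lower (-0.81). The homing list did not pass without Th9 replicate 1 (adjusted p = 0.0806), without background correction (adjusted p = 0.135) or with an offset of 16 (adjusted p = 0.0544). Of 14 T cell identity genes, 1 was higher and 2 lower, against 1 and 3 adjusted over the list alone (adjusted p = 0.012, or adjusted p = 0.155 with an estimated correlation). Cd6, a T cell surface receptor, was lower in Th9 (-1.42). The median of the T cell identity list was -0.17, and turned to 0.005 with arrays scaled to their median (adjusted p = 0.0946), a scaling that moved the median of all genes from 0.012 to 0.135. Relative to that shift the list stood at -0.13.

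Among markers of other cells, Hba-a1 rose in Th9 together with 1 other member of the erythroid and platelet list, the beta globin gene Hbb-b1 (0.64 ± 0.11), while 10 of the 12 measured members did not pass, also adjusted over the list alone. That list passed with a camera adjusted p of 0.0306, with adjusted p = 0.385 with an estimated correlation, and did not pass without Th9 replicate 1 (adjusted p = 0.0533), with arrays scaled to their median (adjusted p = 0.471) or with no filter on dim probes (adjusted p = 0.061). Of 9 other Hbb-b1 probes 6 passed, but each averaged near background. Of 5 granulocyte markers 1 was higher, Chil3, at least 1.94-fold, as the Th1 level was not above background (list adjusted p = 0.165). Of 17 B cell and plasma cell genes, 4 were higher in Th9 and 2 lower, and the list did not pass (adjusted p = 0.0905). Cd74, the MHC class II invariant chain, was higher (1.01 ± 0.12), whereas the immunoglobulin light chain Igkc differed by 0.16 ± 0.12 and did not pass. Cytotoxic effector genes (2 higher and 5 lower of 18), cell cycle genes (0 of 32 past the threshold) and NF-kB pathway genes (5 higher and 1 lower of 27) did not pass as lists, at adjusted p of 0.0996, 0.886 and 0.0832. Within them Nkg7, a cytotoxic granule protein, was lower in Th9 (-1.69), and Traf6, an adaptor of NF-kB signalling, was higher (0.52 ± 0.11, adjusted p = 0.00247), with 1 other Traf6 probe at 0.36 that passed and 1 at 0.10 that did not. The Traf6 call ended without background correction (0.60, adjusted p = 0.139). The cytotoxic list had a median of 0.03 but a mean of -0.20 and a test that pointed down. Gzmb (-0.23), Prf1 (-0.19), Eomes (0.21), Il7r (-0.22) and Pdcd1 (-0.18) did not pass in this comparison.

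In all, 1295 of 12093 genes (10.7%) differed between Th9 and Th1 at an adjusted p below 0.05 in limma's moderated test with Benjamini-Hochberg adjustment, 708 higher and 587 lower in Th9. With arrays scaled to their median the split was 1543 higher and 186 lower. Without background correction, a setting that also drops the offset and sets values below 1 to 1, the count was 236. With an offset of 16 it was 729. Without Th9 replicate 1 the count was 781, and without Th9 replicate 2 it was 829. Of 84 named genes called here, 47 no longer passed when background correction and the offset were left out, among them Chil3, Tbx21, Ifng, Onecut2, Asb2, Ccl5, Cd27, Fos, Ccr8, Cxcr6, Traf6 and Cd74.

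**Figure D1:**
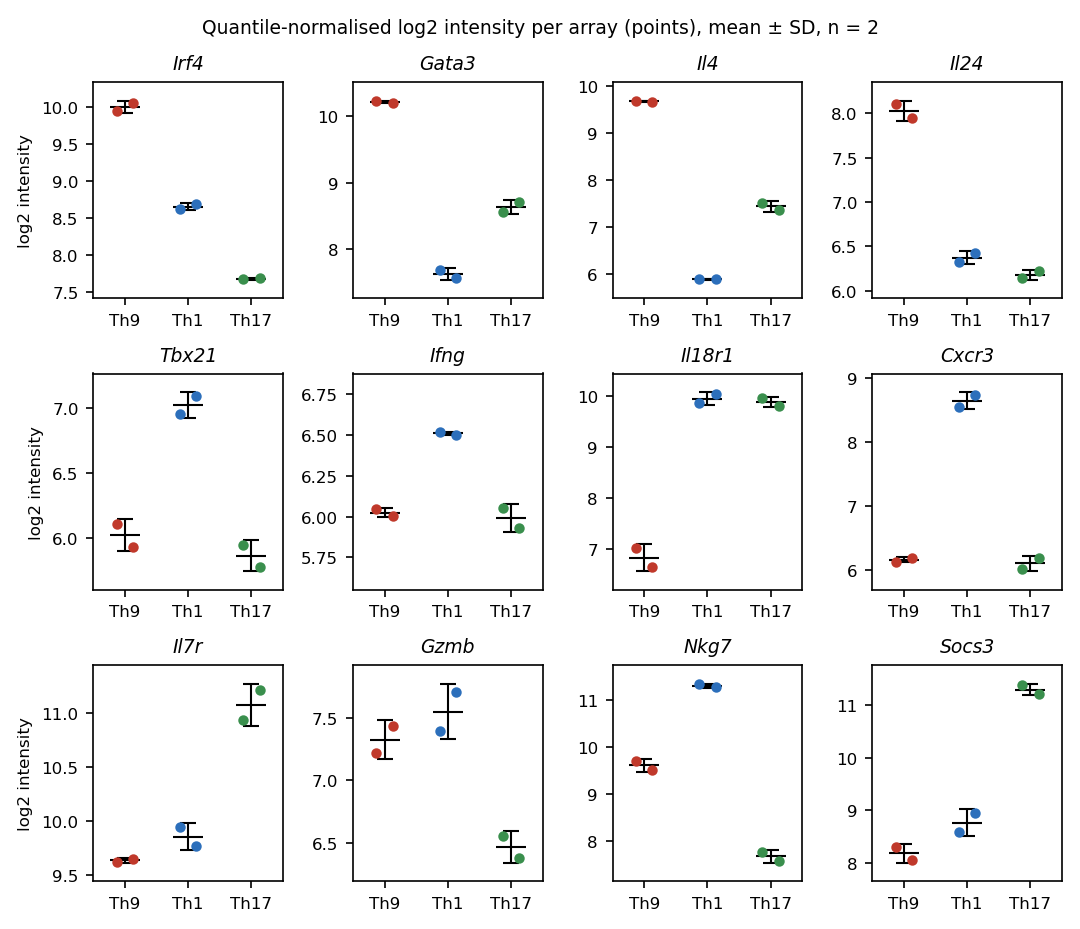
Log2 intensity after normalization of 12 named genes on each of the 6 arrays. Points are arrays, horizontal bars the mean and error bars the SD of 2 arrays, and each panel has its own vertical axis, which does not start at 0. Irf4, Gata3, Il4 and Il24 were highest in Th9, Tbx21, Ifng, Cxcr3 and Nkg7 in Th1, and Il7r and Socs3 in Th17.

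The comparison of Th9 with Th17 cells asks the same of the other pair that holds Th9. Th9 cells had higher levels of Irf4 (2.32 ± 0.11), Il4 (2.23 ± 0.11), Il24 (1.84 ± 0.11) and Gata3 (1.58 ± 0.11). Th17 cells had higher levels of Socs3, an inhibitor of cytokine signalling (-3.12 ± 0.13 in Th9 against Th17), Il18r1 (-3.05 ± 0.13), the interleukin 6 receptor chain Il6ra (-2.01 ± 0.11) and Il7r, the interleukin 7 receptor of long-lived T cells (-1.44 ± 0.12). Among 17 B cell and plasma cell markers, 10 were higher and 1 lower in Th9, in samples sorted on CD45.1 and CD4. The increases were led by Igkc (3.59 ± 0.12) and Cd74 (2.80 ± 0.12). With an estimated correlation the list did not pass (camera adjusted p = 0.0569).

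The other genes with the largest increases in Th9 were Akr1c18 (4.30 ± 0.12), Asb2 (3.28 ± 0.13), S100a1, a calcium-binding protein (3.18 ± 0.11), Cox6b2 (2.86 ± 0.12), Hba-a1 (2.83 ± 0.11), Batf3, an AP-1 family transcription factor (2.83 ± 0.11), the immunoglobulin light-chain segment Iglv1 (2.79 ± 0.11) and Ckmt1, a mitochondrial creatine kinase (2.75 ± 0.11). The other genes with the largest decreases were Ramp1, part of the receptor for calcitonin gene-related peptide (-2.76 ± 0.12), Ripor2 (-2.66 ± 0.11), Emp1 (-2.61 ± 0.11), Bambi-ps1 (-2.48 ± 0.11), Trib2 (-2.36 ± 0.12), Alox5ap, the activating protein of 5-lipoxygenase (-2.31 ± 0.12), Vsir, the inhibitory ligand VISTA (-2.29 ± 0.12), and Sgk1, a salt-sensing kinase (-2.22 ± 0.11). Of 4 other Ripor2 probes 3 passed in the same direction and 1 near background gave 0.02.

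Of 18 measured memory and quiescence genes, 14 were lower in Th9 than in Th17 and 2 higher, against 15 and 2 adjusted over the list alone (adjusted p = 1.57e-11, or adjusted p = 0.0569 with an estimated correlation). Besides Il6ra and Il7r, they included Klf2, a transcription factor of quiescence (-1.92), Cd27 (-1.88) and Bcl6, a repressor that guides follicular helper cells (-1.65). Of 12 Th9 and type 2 helper genes, 7 were higher and 0 lower, and 9 were higher adjusted over the list alone (adjusted p = 9.88e-10, or adjusted p = 0.0569 with an estimated correlation). Of 12 regulatory T cell genes, 8 were higher and 0 lower, also adjusted over the list alone (adjusted p = 5.71e-09, or adjusted p = 0.0569 with an estimated correlation). They were led by Ebi3, a subunit of interleukins 27 and 35 (2.46), Tnfrsf4 (1.89), Tnfrsf18, the costimulatory receptor GITR (1.55), and Gpr83 (1.44).

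Of 11 measured Th17 genes, 6 were lower in Th9 and 0 higher, and 6 were lower and 1 higher adjusted over the list alone (adjusted p = 0.0089, or adjusted p = 0.151 with an estimated correlation). Rora, a nuclear receptor, changed by -0.86 and Stat3, a transducer of interleukin 6 signals, by -0.78. Of 18 cytotoxic effector genes, 7 were higher and 2 lower, also adjusted over the list alone (adjusted p = 0.00093, or adjusted p = 0.1 with an estimated correlation). Nkg7 was higher in Th9 (1.93), as were Cst7, cystatin F (1.47), Ccl5 (1.14) and Gzmb, granzyme B (0.86 ± 0.13), whereas Klrd1, an NK cell receptor chain, was lower (-1.19). Eomes, a transcription factor of effector cells, was higher by 0.36 (adjusted p = 0.0396). This call ended without Th9 replicate 2 (adjusted p = 0.407), Th17 replicate 1 (adjusted p = 0.22) or Th17 replicate 2 (adjusted p = 0.114), and with arrays scaled to their median (adjusted p = 0.0795).

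Of 20 cytokine receptor genes, 3 were higher and 6 lower in Th9, against 4 and 8 adjusted over the list alone (adjusted p = 0.0268, or adjusted p = 0.323 with an estimated correlation). Ifngr1, an interferon gamma receptor chain, was lower (-1.25). The cytokine receptor list did not pass without background correction (adjusted p = 0.135), with the mean of all probes (adjusted p = 0.116) or with an offset of 16 (adjusted p = 0.0909). Of 17 glycolysis genes, 3 were lower and 0 higher, and 7 were lower adjusted over the list alone (adjusted p = 0.00746, or adjusted p = 0.14 with an estimated correlation). The 3 were Pdk1, a kinase that holds back pyruvate oxidation (-1.26), Egln3, an oxygen-sensing prolyl hydroxylase (-0.94), and Slc2a3, a glucose transporter (-0.92), of which Pdk1 and Egln3 regulate metabolism and are not glycolytic enzymes. The other probes of Pdk1 (-0.24) and Egln3 (-0.32), near background, did not pass. Of 24 oxidative phosphorylation genes, 6 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0089, or adjusted p = 0.14 with an estimated correlation). The larger changes were those of Ndufa4 (0.55) and Ndufa1 (0.54), both respiratory chain subunits. With arrays scaled to their median the oxidative phosphorylation list did not pass (adjusted p = 0.159), nor did Ndufa4 (adjusted p = 0.113) and Ndufa1 (adjusted p = 0.0503), and Ndufa1 did not pass without Th9 replicate 1 (adjusted p = 0.0593).

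Of 17 B cell and plasma cell markers, 10 were higher in Th9 than in Th17 and 1 lower, and 13 were higher and 1 lower adjusted over the list alone (adjusted p = 2.76e-10, or adjusted p = 0.0569 with an estimated correlation). Besides Igkc and Cd74 they included the MHC class II chain H2-Eb1 (1.93) and Mzb1, a chaperone of antibody-secreting cells (1.83). The 1 lower gene was Ighm, the immunoglobulin M heavy chain (-0.57). Of 14 T cell identity genes, 8 were lower in Th9 and 0 higher, and 11 were lower adjusted over the list alone (adjusted p = 5.38e-07, or adjusted p = 0.0673 with an estimated correlation). They included Cd6 (-1.76), the signalling adaptors Lat (-0.91) and Skap1 (-0.63), and Cd2 (-0.54). Of 13 myeloid markers 1 was higher and 1 lower (adjusted p = 0.986), most of them near background. Of 5 granulocyte markers 1 was higher, Chil3, at least 1.96-fold (list adjusted p = 0.742, with a median of -0.07 and a mean of 0.15). Of 12 erythroid and platelet markers Hba-a1 and Hbb-b1 (0.40) were higher (list adjusted p = 0.174), Hbb-b1 not without Th9 replicate 1 (adjusted p = 0.101), Th17 replicate 1 (adjusted p = 0.0865) or Th17 replicate 2 (adjusted p = 0.0625). Cell cycle genes (5 higher and 1 lower of 32) and interferon response genes (0 higher and 7 lower of 23) did not pass as lists, at adjusted p of 0.158 and 0.0711. Tbx21 (0.16), Ifng (0.03), Prf1 (-0.02), Pdcd1 (0.04) and Traf6 (0.30) did not pass. Traf6 passed in the fit of these 4 arrays alone (adjusted p = 0.0492).

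In all, 2296 of 12093 genes (19%) differed between Th9 and Th17 at an adjusted p below 0.05, 1214 higher and 1082 lower in Th9. With arrays scaled to their median the split turned to 699 higher and 924 lower. Without background correction the count was 675. The count was 1513 without Th9 replicate 1, 1499 without Th17 replicate 1 and 1424 without Th17 replicate 2. Of 97 named genes called here, 36 no longer passed when background correction and the offset were left out, among them Chil3, Gzmb, Eomes, Stat3, Ndufa4, Ndufa1, Lat, Skap1, Cd2 and Hbb-b1.

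**Figure D2:**
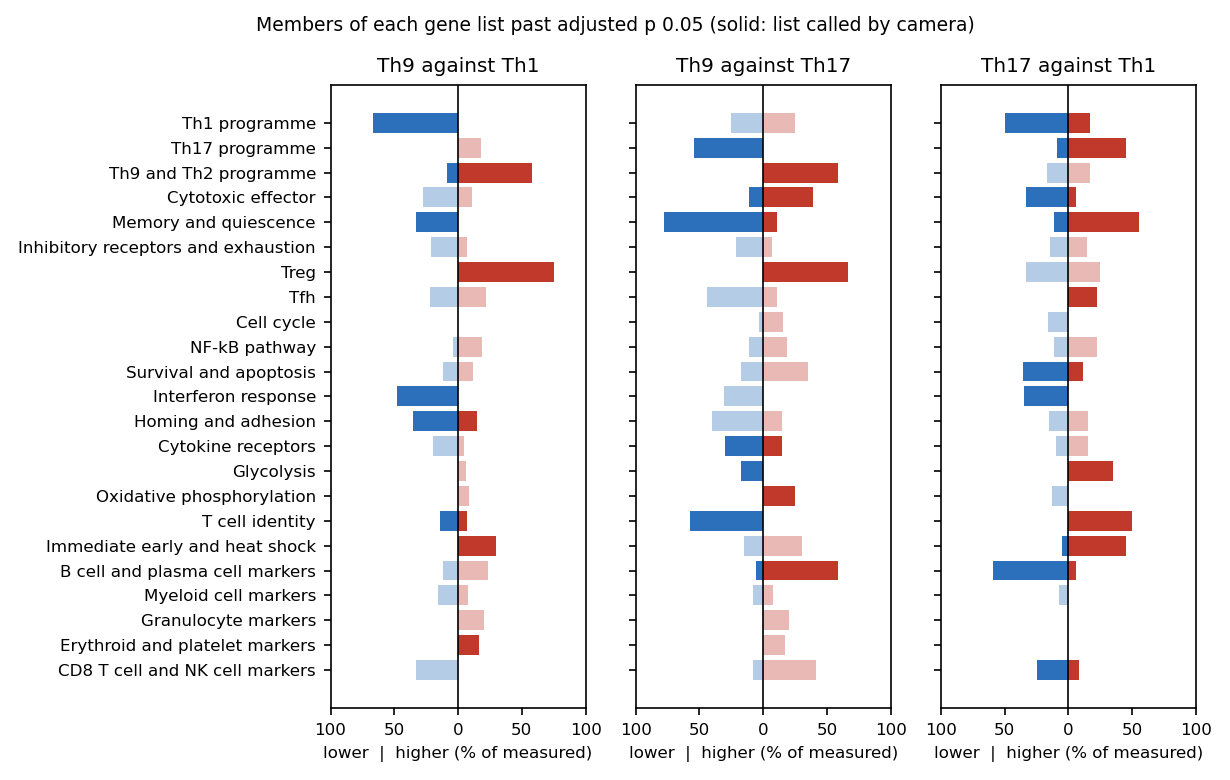
Share of the measured members of each of 23 gene lists that were higher (right, red) or lower (left, blue) in the subset named before the word against, in percent, at an adjusted p below 0.05 over all genes. Solid bars mark lists past the camera test and pale bars those not past it. Regulatory T cell genes were higher in Th9 in both of its comparisons, at 9 and 8 of 12 genes, and memory genes were lower, at 6 and 14 of 18. The median of the T cell identity list in Th9 against Th1 and of the survival list in Th17 against Th1 turned with arrays scaled to their median, which moved all genes, and relative to all genes stood at -0.13 and 0.035. With an estimated correlation, a test limited by the 3 residual degrees of freedom, 0 of the 23 lists passed in any comparison.

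The comparison of Th17 with Th1 cells covers the remaining pair. Th17 cells had lower levels of Nkg7 (-3.62 ± 0.12), Cxcr3 (-2.54 ± 0.11) and Gzmb (-1.09 ± 0.13), and Tbx21 was at least 1.96-fold lower in Th17, where it was not above background. Th17 cells had higher levels of Socs3 (2.54 ± 0.13), Il6ra (2.34 ± 0.11) and Il7r (1.22 ± 0.12). Ifng was lower in Th17 (-0.52 ± 0.11), where 1 of the 2 arrays was not above background, so the size of this change depends on the floor. Irf4 was lower (-0.97 ± 0.11) while Gata3 was higher (1.0 ± 0.11) in Th17. Among 17 B cell and plasma cell markers, 10 were lower and 1 higher in Th17 than in Th1, with Igkc at -3.43 ± 0.12. With an estimated correlation the list did not pass (camera adjusted p = 0.0569).

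The other genes with the largest increases in Th17 were Myo6 (3.35 ± 0.12), Sgk1 (2.97 ± 0.11), St6gal1 (2.88 ± 0.13), Ramp1 (2.51 ± 0.12), Cysltr1, a cysteinyl leukotriene receptor (2.34 ± 0.11), Alox5ap, which acts in leukotriene synthesis (2.27 ± 0.12), Igfbp4 (2.19 ± 0.12) and Cyp2s1 (1.91 ± 0.13). The other genes with the largest decreases were Serpine2, a protease inhibitor (-3.14 ± 0.11), Plac8 (-3.04 ± 0.11), the interferon-induced membrane proteins Ifitm3 (-2.83 ± 0.11) and Ifitm1 (-2.79 ± 0.11), P2ry14 (-2.81 ± 0.11), Batf3 (-2.48 ± 0.11) and Onecut2 (-2.42 ± 0.12). Ifitm genes are near-identical in part, and 1 probe each near background of Ifitm1 (-0.21), Onecut2 (-0.03) and Ramp1 (0.23) did not pass, whereas the other probes of Ifitm1 and Onecut2 passed in the same direction.

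Of 12 Th1 genes, 6 were lower in Th17 and 2 higher, against 7 and 2 adjusted over the list alone (adjusted p = 5.61e-06, or adjusted p = 0.0749 with an estimated correlation). They included Ccl5 (-1.99) and Lta, lymphotoxin alpha (-1.16). Of 11 Th17 genes, 5 were higher and 1 lower, and 6 were higher and 1 lower adjusted over the list alone (adjusted p = 0.000459, or adjusted p = 0.0994 with an estimated correlation). They included Tmem176b (1.69) and Tmem176a (1.41), membrane proteins expressed with the Th17 programme, and Rora (0.95). The 1 lower gene was Ccr6 (-0.485), whose other probe, near background, gave 0.11 and did not pass. Tmem176b and Tmem176a were also higher in Th9 than in Th1, the latter by 0.96, so they did not mark Th17 cells alone. Of 18 cytotoxic effector genes, 6 were lower and 1 higher, also adjusted over the list alone (adjusted p = 2.31e-05, or adjusted p = 0.0778 with an estimated correlation). Fasl, the Fas ligand, was at least 2.9-fold lower in Th17, where it was not above background, and Ctsw, cathepsin W, was lower (-1.10).

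Of 18 memory and quiescence genes, 10 were higher in Th17 and 2 lower, against 11 and 2 adjusted over the list alone (adjusted p = 1.92e-07, or adjusted p = 0.0636 with an estimated correlation). Besides Il6ra and Il7r they included Bcl6 (1.39) and Klf2 (1.18). Of 23 interferon response genes, 8 were lower and 0 higher, against 9 lower and 1 higher adjusted over the list alone (adjusted p = 1.37e-05, or adjusted p = 0.0749 with an estimated correlation). They included Gbp2 (-1.95), Igtp (-1.85) and Usp18 (-1.62). Of 17 glycolysis genes, 6 were higher and 0 lower, and 8 were higher adjusted over the list alone (adjusted p = 0.00013, or adjusted p = 0.0932 with an estimated correlation), among them Egln3 (1.68), Slc2a3 (1.22), Pdk1 (0.94) and Hk1, a hexokinase (0.54). The other probes of Egln3 (0.27) and Pdk1 (0.20), near background, did not pass. Of 20 immediate early and heat shock genes, 9 were higher and 1 lower, and 10 were higher and 1 lower adjusted over the list alone (adjusted p = 0.000314, or adjusted p = 0.0932 with an estimated correlation). They were led by Zfp36, which destabilizes cytokine messenger RNAs (1.04), Fos (0.98) and Ier3 (0.98).

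Lists that passed by a narrower margin were the follicular helper, survival, and CD8 and NK cell lists. Of 9 follicular helper genes, Bcl6 (1.39) and Il21 were higher in Th17 and 0 lower, and 4 were higher adjusted over the list alone (adjusted p = 0.0327, or adjusted p = 0.226 with an estimated correlation). Il21, a cytokine of follicular helper and Th17 cells, was at least 1.24-fold higher and did not pass without Th17 replicate 1 (adjusted p = 0.108). The follicular helper list did not pass without Th1 replicate 1 (adjusted p = 0.0813) with arrays scaled to their median (adjusted p = 0.0697), without background correction (adjusted p = 0.135), with the mean of all probes (adjusted p = 0.0644) or with an offset of 16 (adjusted p = 0.0631). Of 17 survival and apoptosis genes, 6 were lower and 2 higher, against 7 and 2 adjusted over the list alone (adjusted p = 0.0222, or adjusted p = 0.294 with an estimated correlation), Fasl among the lower. The survival list had a median of -0.13, which turned to 0.18 with arrays scaled to their median (adjusted p = 0.156), or 0.035 relative to the shift of 0.15 that this scaling gives all genes. It did not pass without Th1 replicate 1 (median -0.08, adjusted p = 0.064), without Th17 replicate 1 (median -0.02, adjusted p = 0.0899) or with the mean of all probes (adjusted p = 0.0592). Of 12 CD8 and NK cell markers, 3 were lower and 1 higher, against 5 and 1 adjusted over the list alone (adjusted p = 0.0154, or adjusted p = 0.287 with an estimated correlation), and the list did not pass without Th1 replicate 1 (adjusted p = 0.093). Klrd1 was higher in Th17 (0.56), Klra3 was lower (-0.58), and of 3 Cd8b1 probes 2 were lower (-1.10, the brightest, and -0.43) and 1 higher (0.36).

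Of 17 B cell and plasma cell markers, 10 were lower in Th17 than in Th1 and 1 higher, against 11 and 1 adjusted over the list alone (adjusted p = 2.76e-10, or adjusted p = 0.0569 with an estimated correlation). They included H2-Eb1 (-1.79), Cd74 (-1.79) and the MHC class II chain H2-Aa (-1.49). Of 14 T cell identity genes, 7 were higher in Th17 and 0 lower, also adjusted over the list alone (adjusted p = 0.00102, or adjusted p = 0.103 with an estimated correlation), led by Cd2 (0.95). Of 13 myeloid markers 1 was lower, Mpeg1 (-0.71), and of 12 erythroid and platelet markers 0 passed, with 0 also adjusted over the list alone (camera adjusted p = 0.485 for each list). The regulatory T cell list (3 higher and 4 lower of 12), the inhibitory receptor list (2 higher and 2 lower of 14) and the granulocyte list (0 of 5 past the threshold) did not pass, at adjusted p of 0.986, 0.952 and 0.485. The inhibitory receptor list had a median of -0.10 and a mean of 0.07. Within the regulatory T cell list Nrp1 was higher in Th17 (1.52) and Ebi3 lower (-1.49). Eomes (-0.15), Prf1 (-0.17), Pdcd1 (-0.23) and Traf6 (0.22) did not pass in this comparison, Traf6 passing with arrays scaled to their median (adjusted p = 0.00798).

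In all, 1807 of 12093 genes (14.9%) differed between Th17 and Th1 at an adjusted p below 0.05, 910 higher and 897 lower in Th17. With arrays scaled to their median the split was 2488 higher and 245 lower, and the median of all genes was 0.15. Without background correction the count was 314, and with an offset of 16 it was 1114. Without Th17 replicate 1 the count was 1116, and without Th17 replicate 2 it was 998. Of 88 named genes called here, 40 no longer passed when background correction and the offset were left out, among them Tbx21, Ifng, Gzmb, Ramp1, Onecut2, Ctsw, Klf2, Hk1, Zfp36, Fos, Il21, Klrd1, Klra3 and Mpeg1.

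Genes that set Th9 apart from both other subsets numbered 453 higher and 306 lower, or 458 and 102 with arrays scaled to their median, 76 and 46 without background correction, and 264 and 165 with an offset of 16. Akr1c18, Hba-a1, Penk, Il4, Asb2, Gata3, Il24 and Irf4 were higher in Th9 than in either, and Il18r1 and Cd6 were lower. The largest decrease in both comparisons was that of AA467197 (-3.84 and -3.39), which the naming rule passes over for its provisional symbol and which was chosen after its values were seen. Itgae, Gpr83, Tnfrsf4, Tnfrsf18, Ebi3, Izumo1r, Tgfb1 and Il2ra of the regulatory T cell list were higher in Th9 in both comparisons. So were Gata3, Il4, Il24, Irf4, Ccr8 and Il10 of the Th9 and type 2 helper list. Independent lists of these sizes would share 71.1 genes that are higher and 52.5 that are lower. Genes higher than one subset and lower than the other numbered 30 and 29, against 63.3 and 58.9 from independent lists. In 100 simulations in which no gene differed between any kinds, 0.01 genes on average and at most 1 passed in both in the same direction. Without effects few genes pass in either comparison, so this low count was fixed by the setting. It cannot show how much of the overlap comes from the shared Th9 arrays. The 2 Th9 arrays could not be divided between the comparisons, so part of the excess may come from the shared arrays. The number of genes apart from both was 478 without Th9 replicate 1 and 484 without Th9 replicate 2, against 759 from the 6 arrays.

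**Figure D3:**
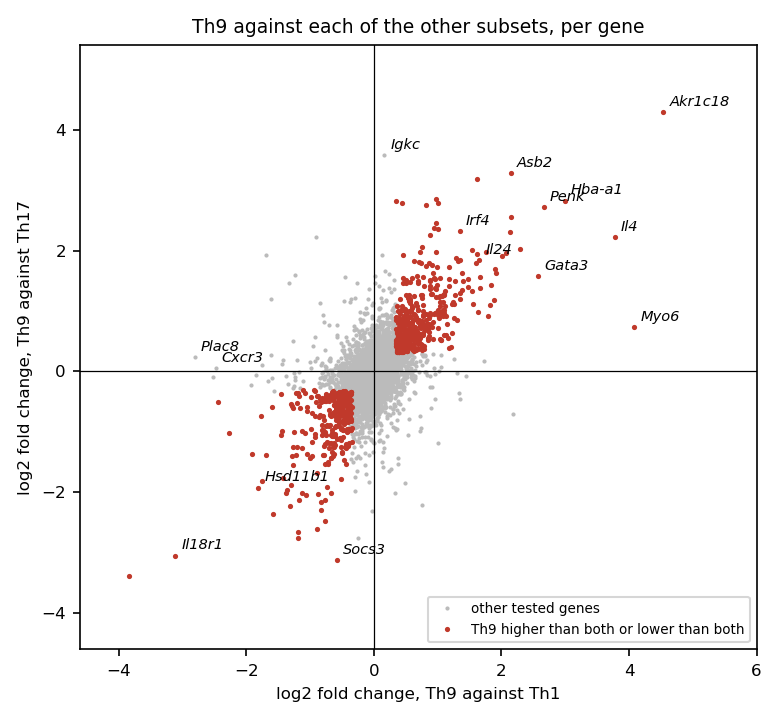
Log2 fold change of each tested gene in Th9 against Th1 (horizontal) and Th9 against Th17 (vertical). Red points are the 453 genes higher and the 306 genes lower in Th9 than in both other subsets, and grey points are the other tested genes. Akr1c18 lies farthest to the upper right, at 4.54 and 4.30, while Igkc lies near the vertical axis, at 0.16 and 3.59.

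**Figure D4:**
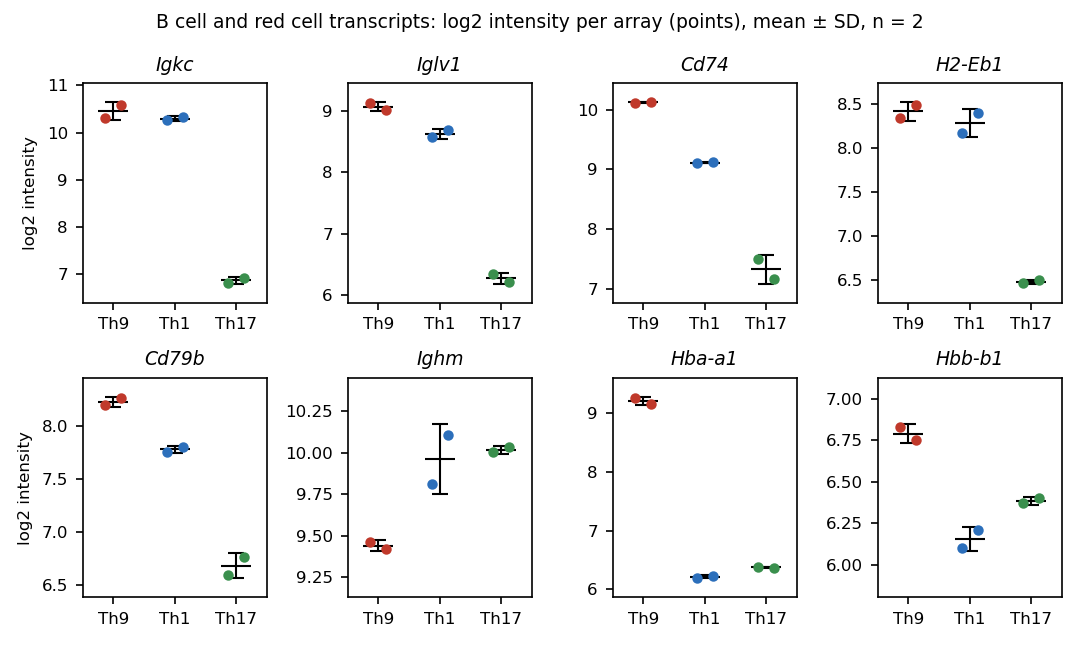
Log2 intensity after normalization of B cell transcripts (Igkc, Iglv1, Cd74, H2-Eb1, Cd79b, Ighm) and globin genes (Hba-a1, Hbb-b1) on each of the 6 arrays. Points are arrays, horizontal bars the mean and error bars the SD of 2 arrays, and each panel has its own vertical axis, which does not start at 0. Both Th17 arrays lie below the other 4 arrays for Igkc, Iglv1, Cd74, H2-Eb1 and Cd79b, and both Th9 arrays lie above the other 4 for Hba-a1.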

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

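The normexp offset of 16 was chosen after seeing the data, and the other alternatives were planned. Of 4645 alternative values of 292 gene results, 4309 kept direction and side of the threshold, 315 no longer passed, 7 newly passed and 14 reversed, none of them a called gene. Of 496 alternative values of 31 list results, 475 kept both, 19 no longer passed and 2 reversed. Without background correction 236 (Th9 against Th1), 675 (Th9 against Th17) and 314 (Th17 against Th1) genes passed, and 122 set Th9 apart from both. With the offset of 16 the counts were 729 for Th9 against Th1, 1114 for Th17 against Th1 and 429 for both. A 2-fold minimum left 171, 322, 188 and 91 by construction. With arrays scaled to their median 2733 genes passed in Th17 against Th1. An estimated correlation, a test limited by the 3 residual degrees of freedom, left 0, 0 and 0 lists, and fry called 17 in Th9 against Th1. Except for the 2-fold minimum the cause was not tested.

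With arrays scaled to their median the list medians of T cell identity (Th9 against Th1, 0.005) and survival (Th17 against Th1, 0.184) reversed, as did Gzmb (0.042), Il7r (0.028), Prf1 (0.002) and Mcm7 (0.034) in Th9 against Th1 and Prf1 (0.171) in Th17 against Th1. This scaling moved the median of all genes to 0.135 and 0.15 in those comparisons, about the size of these changes, and relative to it T cell identity stood at -0.131 and survival at 0.035. With the mean of all probes Hbb-b1 reversed in Th17 against Th1 (-0.018). Leaving out 1 array, whose partner is then assumed to vary like the other groups, gave 781 to 1177 genes for Th9 against Th1, 1424 to 2608 for Th9 against Th17, 998 to 1683 for Th17 against Th1 and 478 to 669 for both. The arrays that moved a count over 1.5 times were Th9 replicate 1 (781, 1513 and 478 without it), Th9 replicate 2 (829 and 484), Th17 replicate 1 (1499 and 1116) and Th17 replicate 2 (1424 and 998). Genes near background that changed sign ranged as follows: Il17a -0.188 to 0.041 (Th9 against Th1), -0.066 to 0.132 (Th9 against Th17) and -0.222 to 0.007 (Th17 against Th1), and in Th9 against Th17 Ifng -0.026 to 0.093, Pdcd1 -0.003 to 0.09 and Prf1 -0.052 to 0.016. With a replicate block 1258, 2249 and 1769 genes passed and 730 set Th9 apart from both. Quantities equal to the analysis as reported (normexp without negative controls, the value table) were not run separately, and neqc was not run for lack of detection p-values. Signal over background limits dim genes: the offset of 16 changed folds by a median ratio of 1.14, and no correction by 1.29, with 42 and 97 of 269 called values moved over 1.5 times. Without correction Tbx21 in Th9 against Th1 went to -4.32 and Onecut2 to -6.95, and neither passed.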

Other observations

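All tests in this part were chosen after the result they concern was seen. Among 17 B cell and plasma cell markers, 10 were higher and 1 lower in Th9 than in Th17, and 10 were lower and 1 higher in Th17 than in Th1. With an estimated correlation the list passed in neither comparison (camera adjusted p = 0.0569 in each). The samples were sorted on CD45.1 and CD4, a sort that would remove B cells. Mean log2 levels of Igkc were 10.45 in Th9, 10.29 in Th1 and 6.86 in Th17, whereas Ighm was 9.44, 9.96 and 10.02. Of 11 measured immunoglobulin light-chain variable genes, 5 were higher in both Th9 and Th1 than in Th17. The bar set for B cells mixed into the Th9 and Th1 samples was a majority of these genes, and it was not reached. With the level of Ighm in Th17 as well, such mixing stays open. Against a lower share of T cells with every other cell type raised alike, 1 of 13 myeloid markers was higher in Th9 than in Th17 and 10 of 17 B cell markers were (Fisher exact p = 0.0067), and of those averaging above a log2 of 6.5, 0 of 4 and 9 of 10. This was not taken to settle it, since the counts had been seen before, genes of a list are not independent, and 4 well-measured myeloid markers are few. B cells of a single make-up as the only source of both Cd74 and Igkc are argued against, since the excess over Th17 was 2.43 times as large in Th9 as in Th1 for Cd74 (2.42 to 2.44 over 4 array pairs) and 1.13 times for Igkc (0.986 to 1.29). The argument is weak, as the 4 pairs come from 2 arrays per kind, which may be technical repeats. The ranges also leave out the spread of the Th17 arrays.

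Hba-a1 was higher in Th9 than in both other subsets, and red cell RNA in the Th9 samples may be a source, which the same sort would remove. Among 11 other measured erythroid and platelet markers 1 was higher than in both, Hbb-b1. Averaged over the 6 arrays the 11 lay below a log2 of 6.5, near background, and Alas2 was detected on 0 arrays, so red cell RNA and expression in the sorted cells cannot be told apart.

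The lists of MHC class I, cholesterol synthesis and ERK target genes were written after single genes drew attention, and each was tested without those genes, adjusted over 9 tests. The lists written beforehand were adjusted over 69 tests, so the adjusted p-values here cannot be compared with theirs. MHC class I and peptide loading genes without H2-Q8 were lower in Th9 than in Th1, 18 of 20 (adjusted p = 1.99e-27, or adjusted p = 0.011 with an estimated correlation), and 16 of 20 were lower in Th17 than in Th1 (adjusted p = 4.96e-16, or adjusted p = 0.0128 with an estimated correlation). Th9 and Th17 differed less, with 8 of 20 lower in Th9 (adjusted p = 0.000392, or adjusted p = 0.0592 with an estimated correlation), so much of this may be a higher level in Th1, and near-identical members may share signal. Cholesterol synthesis genes without Hsd17b7 were higher in Th9 than in Th1, 7 of 17 (adjusted p = 1.04e-05, or adjusted p = 0.0462 with an estimated correlation), and did not pass against Th17 (adjusted p = 0.368), while 4 of 17 were higher in Th17 than in Th1 (adjusted p = 0.00117, or adjusted p = 0.0628 with an estimated correlation). Dusp6, Dusp4 and Egr genes were higher in Th9, but the list of the 8 other ERK target genes, with 1 higher and 1 lower in each comparison, did not pass against Th1 (adjusted p = 0.254) or Th17 (adjusted p = 0.708), so a wider rise of ERK targets stays open. A list of MHC class II genes was tested as well, with the genes that prompted it, Cd74 among them, still in it, so its result (9 higher and 1 lower of 12 in Th9 against Th17, adjusted p = 2.73e-08 over 12 tests, or adjusted p = 0.0239 with an estimated correlation; 1 higher and 7 lower in Th17 against Th1, adjusted p = 3.97e-07, or adjusted p = 0.0239; 3 higher and 0 lower in Th9 against Th1, adjusted p = 0.00155, or adjusted p = 0.0513) partly restates the B cell markers.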
